A study of Homo sapiens with 24 samples.

How the data were processed

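DNA G-quadruplexes, secondary structures of guanine-rich DNA, were mapped with the SG4 nanobody by chromatin immunoprecipitation and sequencing in U2OS and K562 cells. Per the labels, each line had 3 biological replicates, lettered A to C, with 3 technical libraries and 1 input each. The 18 SG4 libraries each came with a list of peaks, and the 6 input libraries were not analysed here because no values for them were among the files used. Lists of stretches per biological replicate and per line were also deposited. Per the submitters' processing notes, the authors used FastQC, cutadapt, BWA, Picard, MACS2 and bedtools with the hg38 genome. Their versions and settings were not given in the sources used here. Per the names of the deposited peaks, peaks were called for each library on its own. The culture notes name an SG11 experiment where all other labels name SG4, and SG4 is used throughout.

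The deposited peak lists give, as the authors' own values from MACS2, a fold enrichment over background, a -log10 p, a -log10 q and a score per peak, which is 10 times the -log10 q rounded down. The deposited stretches give the start and end of each stretch in base pairs and no signal. All lists stop at a -log10 q of 1.30, so a missing peak means a signal under that threshold and not its absence. The files hold no read counts, so the depth of each library is unknown. Intervals for shares of sites are 95% Wilson intervals and cover counting error only.

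Peaks on chromosomes 1 to 22 and X were used. A site was a stretch covered by peaks of at least 2 of the 3 technical libraries of a biological replicate. A line's consensus sites were stretches covered by the sites of at least 2 of its 3 biological replicates, with touching stretches joined. A promoter was the 1 kb to either side of any start of a protein-coding transcript in GENCODE release 44, which gave 19626 protein-coding genes. A canonical motif was 4 runs of 3 or more G with loops of 1 to 7 bases, on either strand. Coordinates count from 1 and include both ends. Folds were never compared between libraries: each peak was given its percentile within its own library, and a gene took the best peak of its promoter, or 0 where a library had none.

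Between lines, the biological replicate was the unit and exact two-sided permutation tests of 3 against 3 were used, for which the smallest possible p is 0.1. Shares of sites were tested against 100 shuffles of the sites along their own chromosomes outside assembly gaps, one-sided, for which 0.0099 is the smallest p the shuffles can give. Similarity of libraries was the Jaccard index of base pairs under peaks, tested over the 10 splits of the 6 biological replicates. A promoter was called restricted to a line when it had a site in all 3 of that line's biological replicates and no peak in any of the 9 libraries of the other. The 11 gene lists were compared with all other protein-coding genes by two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over lists and lines. Between lines, the same test was run among genes with a promoter site in exactly 1 line, adjusted over the lists. Genes, not samples, are the units of these tests.

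The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the members of the fixed lists; for each line, the 12 restricted promoters with the highest mean percentile over its 9 libraries; the 12 promoters with a peak in all 18 libraries and the highest mean percentile; and the 3 sites over 10 kb from any gene start with the highest percentile in each line and in both. The lists were promoter quadruplex genes, erythroid and haematopoietic genes, mesenchymal and osteoblast genes, neuronal genes, hepatocyte genes, ribosomal protein genes, housekeeping genes, cell cycle genes, quadruplex helicase genes, HOX genes and 9p21 genes. Families of genes that share a symbol prefix, and the histone genes, were tested after the counts per chromosome had been seen. Values of some genes that the rule names are not reported here.

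The alternatives were stricter peak lists, lists of equal length, all contigs, stricter agreement between technical or biological replicates, each biological replicate left out, other promoter windows, other motif definitions, fixed site widths, other backgrounds, a larger overlap, ranking by q value, another measure of similarity and the deposited line lists. Use of the deposited line lists for shared sites, promoter and motif shares and gene lists, the lists without the shortest library and the family tests were added later. The deposited line lists were not used for restricted promoters. The labels do not say that the letters pair the lines. A check of that pairing and the values with it are given once, in the closing section.

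The motif search was checked on 3600 simulated windows against a second implementation, with 0 mismatches, and the coverage step on 50 simulated triplets, with 0 mismatches. Tested on simulated data, the shuffle test passed 0.05 in 1 of 10 runs with no planted motifs and in 10 of 10 runs with motifs planted in 5% of sites. The test of a 30-gene list passed in 1 of 100 runs with no effect, in 46 of 100 runs at a 1.5-fold share and in 97 of 100 runs at a 2.0-fold share. Of 200 promoters made restricted to U2OS, 200 were recovered. They were made to meet the rule, so this recovery was fixed in advance and checks only that the rule was applied as written. Of the 19426 other promoters, 6 and 2 were called for U2OS and K562. These calls come from simulated lists and give no rate of false calls for the real ones, where pool and depth may differ between lines. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and bedtools 2.31.1.

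Peaks on the mitochondrial genome and on unplaced contigs were left out of the comparisons. The lists of the 2 lines carry different sequencing pool names, so pool and line cannot be told apart.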

Results

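SG4, a nanobody that binds folded DNA G-quadruplexes, was used to pull down chromatin from U2OS osteosarcoma cells and K562 chronic myeloid leukaemia cells. Each line was represented by 3 biological replicates, A to C, with 3 technical libraries each, giving 18 lists of peaks. The lists held 13366 to 29219 peaks per U2OS library and 4259 to 19219 per K562 library. Their read depth is unknown. The median fold over background, as computed by the authors, lay between 5.12 and 5.48 in U2OS libraries and between 5.22 and 6.08 in K562 libraries.

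The number of quadruplex sites in each line was compared first. U2OS replicates held 23088 ± 3102 peaks per library and K562 replicates 12259 ± 3547 (SD, n = 3 biological replicates each), a ratio of 1.88. Sites found in at least 2 of 3 technical libraries numbered 20612 ± 2802 per U2OS replicate and 10826 ± 3101 per K562 replicate (SD, n = 3), a ratio of 1.90. The consensus of U2OS held 19424 sites over 3.27 Mb, of which 11987 stretches were found in all 3 replicates. The consensus of K562 held 10169 sites over 1.81 Mb, and 6025 stretches were found in all 3 replicates. Each U2OS replicate exceeded each K562 replicate in both measures, and the exact permutation p was 0.1 for both, the smallest that 3 against 3 allows. With lists of equal length, the ratio of sites per replicate was 0.964. The K562 consensus held 6400 sites without replicate A and 6628 without replicate C, where both remaining replicates had to share a site.

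**Figure D1:**
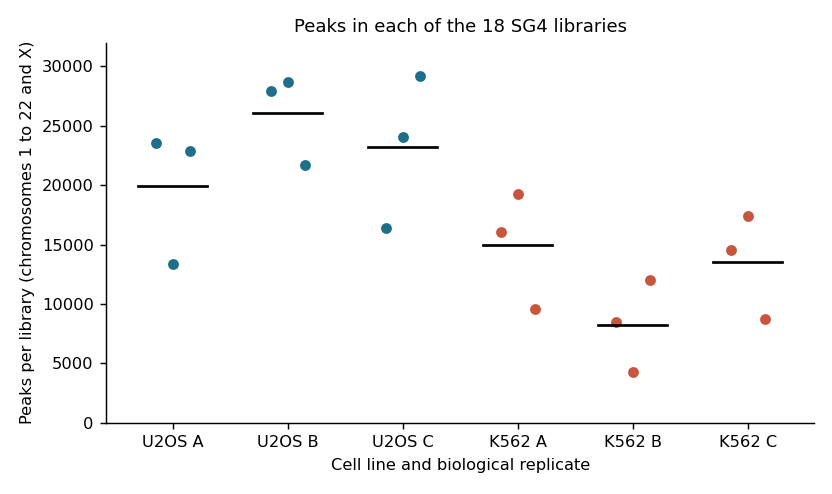
Peaks per library (vertical axis, count on chromosomes 1 to 22 and X) for each biological replicate (horizontal axis). Points are the 3 technical libraries and bars their mean; the lowest U2OS library held 13366 peaks and the lowest K562 library 4259.

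Sharing of sites between the lines was measured next. Of the 10169 K562 sites, 5070 (49.9%) overlapped a U2OS site, against 0.284% of K562 sites shuffled along their chromosomes and 2.42% when promoter sites were shuffled within promoters. The overlap lay mostly at promoters. Shared sites were promoter sites in 82.0% of cases, whereas 30.2% of the sites of U2OS alone and 25.6% of those of K562 alone were. Among promoter sites, 48.9% of those in U2OS and 76.1% of those in K562 were shared, and among the other sites 8.32% and 19.4% were. The overlap exceeded that of all 100 shuffles (one-sided permutation p = 0.0099, the smallest they can give).

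Libraries resembled their own line most. The Jaccard index averaged 0.358 between technical libraries of the same biological replicate (18 pairs, 0.256 to 0.433), 0.328 between replicates of the same line (54 pairs) and 0.145 between lines (81 pairs). Pairs within a line exceeded pairs between lines by 0.183, and the highest of the other splits of the 6 replicates gave -0.0135 (exact permutation p = 0.1, the smallest possible). The difference between technical and biological pairs, 0.0294, was not tested.

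**Figure D2:**
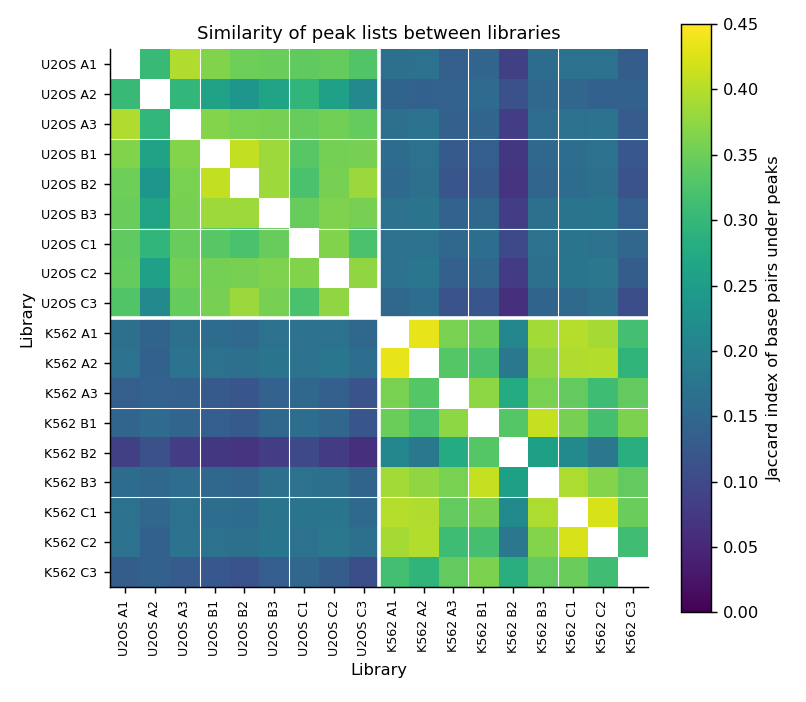
Jaccard index of base pairs under peaks (colour) for each pair of the 18 libraries (both axes). White lines separate biological replicates, the thick line separates U2OS from K562, and pairs within a line average 0.328 between replicates against 0.145 between lines.

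The position of sites relative to genes was examined in each line. Promoters held 43.7% of U2OS consensus sites (8484 of 19424, Wilson interval 43.0% to 44.4%) and 53.7% of K562 sites (5461 of 10169, 52.7% to 54.7%). Shuffled sites lay in promoters in 3.23% and 3.49% of cases, so that the observed shares were 13.5 and 15.4 times as large. Sites clustered just upstream of gene starts: of sites centred within 1 kb of a start, 77.9% in U2OS and 82.8% in K562 lay upstream, with medians of -69 bp and -81 bp. In all, 7315 genes (37.3%) had a promoter site in U2OS and 5445 (27.7%) in K562, and 4611 had one in both. No library listed a peak at 7177 promoters.

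Both promoter shares exceeded all shuffles (one-sided permutation p = 0.0099). Between lines, the promoter share was 42.2% ± 2.28 in U2OS replicates and 51.9% ± 4.00 in K562 replicates (SD, n = 3, exact permutation p = 0.1). The lead of K562, 9.70 percentage points, was 3.28 with lists of equal length.

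A core of 1562 promoters had a peak in all 18 libraries. First of the 12 highest was NAPA, which encodes the alpha-SNAP protein of vesicle fusion, at a mean percentile of 99.5 ± 0.559 in U2OS and 99.1 ± 0.343 in K562 (SD, n = 3). Its sites lay upstream of the gene on chromosome 19, at 47515027 to 47515569 in U2OS and 47515041 to 47515667 in K562 (hg38). EDEM3, a factor of endoplasmic reticulum degradation, reached 99.6 ± 0.193 and 98.6 ± 1.19 at chromosome 1, 184754845 to 184755262 in U2OS. PLAUR, the urokinase receptor gene, had an intronic site in both lines that held GGGGACCGGGCCTAGGGACTGGG at chromosome 19, 43668964 to 43668986. Other members were the corepressor gene SIN3A, the MAX partner gene MXD1, the Integrator subunit gene INTS4, the phosphatase gene MTMR4, the heat shock gene DNAJB1, the adaptor gene SHC1 and BSDC1. All 12 kept a peak in every library with lists of equal length, where the number of such promoters was 262, and among the better-scoring 50% of peaks of each library, where it was 491. The 12 were picked for the highest percentiles and these lists keep the best-scoring peaks. That the 12 were kept was therefore likely from their selection and is no separate support.

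Whether sites recovered with the nanobody held quadruplex-forming sequence was asked next. A canonical motif was present in 11.6% of U2OS sites (2254 of 19424, Wilson interval 11.2% to 12.1%) and 10.3% of K562 sites (1043 of 10169, 9.68% to 10.9%). Shuffled sites held one in 2.00% and 2.20% of cases, giving 5.80-fold and 4.66-fold enrichment. A further 8.31% of U2OS sites and 8.93% of K562 sites held a motif only when loops of 8 to 12 bases were allowed. Motifs with 2 G per run were the only kind in 41.6% and 45.01%, against 27.6% and 30.3% of shuffled sites. None of these was held by 38.4% and 35.8% of sites, against 68.6% and 65.6% of shuffled ones. The sites were rich in G and C, at 59.99% in U2OS and 58.7% in K562, against 41.9% and 42.1% in shuffled sites.

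Motifs, sought over the full width of each peak, were most frequent under the highest peaks. In U2OS the share rose from 6.99% ± 0.869 in the 10% of peaks with the lowest fold to 28.8% ± 5.19 in the 10% with the highest (SD, n = 3). In K562 it went from 7.75% ± 1.44 to 19.7% ± 1.99 (SD, n = 3). Spearman's rho over the 10 groups of peaks had a median of 0.976 in U2OS and 0.939 in K562, and it was above 0 in all 18 libraries. Among U2OS promoter sites, 23.1% of the shared ones and 15.7% of those of U2OS alone held a motif, and among K562 promoter sites 16.7% and 8.58% did. In windows of 200 bp at each site the U2OS order turned, to 19.7% and 30.2%, while K562 kept its order, 19.5% and 14.9%. Shared promoter sites were wider, with medians of 241 bp against 96 bp in U2OS and 198 bp against 109 bp in K562. The shares over full widths are thus not comparable apart from width.

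**Figure D3:**
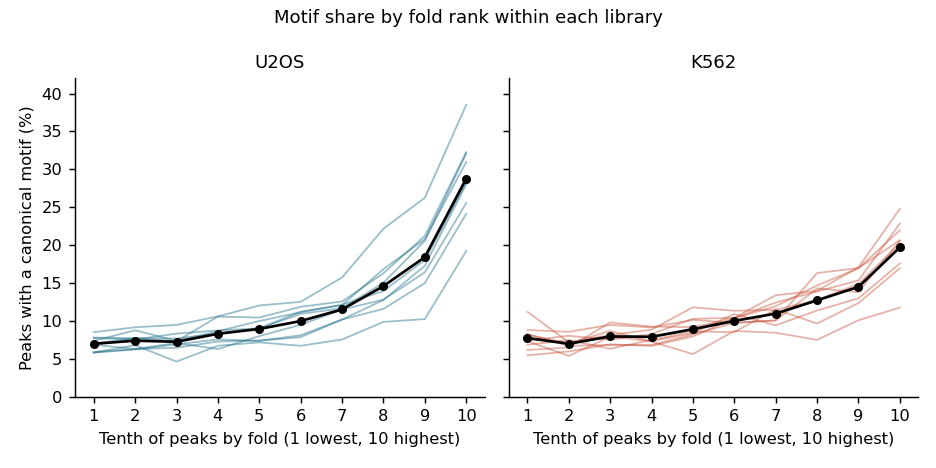
Share of peaks with a canonical motif (vertical axis, %) across 10 equal groups of peaks ordered by fold within a library (horizontal axis), with U2OS on the left and K562 on the right. Coloured lines are the 9 libraries of a line and black points their mean, which is 28.8% in the highest group of U2OS and 19.7% in that of K562.

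The shares with a motif exceeded all shuffles in both lines (one-sided permutation p = 0.0099). Between lines, 11.98% ± 2.17 and 10.6% ± 0.404 of sites per replicate held one (SD, n = 3), a difference within the spread between replicates (exact permutation p = 0.4). That difference of 1.398 percentage points was 9.97 with lists of equal length (exact permutation p = 0.1), and -1.43 with motifs of 2 G per run. It was 2.57 without U2OS replicate A, 0.419 without U2OS replicate C and 3.16 with the better-scoring 50% of peaks (exact permutation p = 0.1, 0.8 and 0.3). Equal lists keep the 4259 best-scoring peaks of each library, on average a smaller part of U2OS lists than of K562 lists. Since the motif share rises with peak rank, this cut alone could raise the U2OS share more. The value of 9.97 therefore does not show a larger difference between lines.

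Promoters restricted to a line were compared to find genes at which the lines differed. In U2OS, 585 promoters had a site in all 3 replicates and no peak in any K562 library. The highest was that of GPR39, a zinc-sensing receptor gene, with a percentile of 98.5 ± 0.759 (SD, n = 3) at chromosome 2, 132416305 to 132416856. This site centred at -224 bp from the start and held the motif GGGTGACGGAGGGTGGGGCGGGGGTGGG. SEPTIN10, a septin gene, and SOWAHC share a site at chromosome 2, 109613896 to 109614375, with 98.3 ± 1.21 and the motif GGGCGCGGGGCGGGGGTGCGGGGGG. BMAL1, a core gene of the circadian clock, reached 92.6 ± 6.62 at chromosome 11, 13277401 to 13277809, and held GGGCGGGGGGCCGGGCCTGGGCCGGCGGGG. ESRP2, which encodes an epithelial splicing regulator, reached 94.5 ± 4.56 with no canonical motif. Others were the kinase gene MAP3K9 (94.98 ± 3.84), RASGEF1C (94.7 ± 1.78), the keratin gene KRT80 (94.3 ± 1.06), the ubiquitin ligase gene TRIM9 (93.3 ± 1.03), PLEKHG4 (92.8 ± 4.98) and WSB2 (92.3 ± 6.48).

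In K562, 124 promoters had a site in all 3 replicates and no peak in any U2OS library. The zinc finger gene ZNF575 led with 94.5 ± 1.60 (SD, n = 3) at an intronic site on chromosome 19, 43533929 to 43534325, which held GGGGAGGGGCCTATGGGCACAGTGGGCGGG. LRIF1, which encodes a partner of heterochromatin protein, reached 92.7 ± 8.07 at chromosome 1, 110963905 to 110964221. The ciliary transport gene IFT172 reached 91.8 ± 2.20 at chromosome 2, 27489684 to 27490010. RHAG, the Rh-associated glycoprotein of red cells, reached 83.9 ± 8.51 at a site in its 5′ UTR on chromosome 6, 49636716 to 49636937, and SLFN14, linked to platelet disorders, reached 85.9 ± 21.5. The others were the neuronal adhesion gene ICAM5 (87.9 ± 5.02), DERL3 of endoplasmic reticulum degradation (82.9 ± 3.97), TEPP (82.8 ± 13.0), the protease gene KLK8 (80.8 ± 13.3), the sialyltransferase gene ST6GAL1 (79.9 ± 8.47), CCDC71L (79.2 ± 2.89) and TMEM191C (83.0 ± 14.3), which has a near-identical copy.

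No test was run on single promoters, since an exact permutation test of 3 against 3 cannot pass 0.05, so restriction is a count and not a call. Restriction rests on the peaks of the libraries and was not checked against the deposited K562 lists. The deposited K562 line list holds 3711 stretches without a rebuilt site, 41.7% of them at promoters, so some U2OS-only promoters may hold such a stretch. With lists of equal length, 102 promoters were restricted to U2OS and 145 to K562. Without U2OS replicate A the U2OS count was 959, and without K562 replicate B the K562 count was 214. Leaving out a replicate removes a requirement of the rule, so these counts could not fall. Of the 12 named K562 promoters, 9 stayed restricted with promoters of 500 bp to either side and 11 with lists of equal length.

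The fixed gene lists were compared with all other protein-coding genes to see which kinds of promoter carried sites. Housekeeping, ribosomal protein and cell cycle genes carried them more often than other genes in both lines. Housekeeping genes had a site in 23 of 25 cases in U2OS and 22 of 25 in K562 (adjusted exact p = 1.9e-07 and 1.1e-08), with the tubulin gene TUBB at percentiles of 95.3 and 98.1. Ribosomal protein genes had one in 23 and 21 of 30 (6.0e-05 and 9.9e-06), among them RPS2 at 92.9 and 96.1. Cell cycle genes had one in 19 and 13 of 21 (4.6e-06 and 0.0030). CDC6, a replication licensing gene, reached 91.0 and 95.2. CCND1, which encodes cyclin D1, was listed in 9 U2OS libraries and in 0 K562 libraries. The other genes had a site in 37.3% of cases in U2OS and 27.7% in K562.

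Genes of the quadruplex helicase list had a site in 9 of 14 cases in both lines, which passed in K562 (adjusted exact p = 0.0094) and not in U2OS (0.0695). The list also holds XPC and FANCD2, repair genes that do not encode helicases, and XPC was listed in all 9 libraries of both lines. Bloom helicase gene BLM was listed in all 9 libraries of both lines. The Werner helicase gene WRN had sites in 3 of 3 K562 replicates at 74.5 ± 14.3 and in 0 of 3 U2OS replicates at 11.6 ± 4.42 (SD, n = 3). The U2OS list passed without U2OS replicate B (0.0111). The K562 list did not pass without K562 replicate A (0.0675) or C (0.0695), nor with sites in all 3 biological replicates (0.0541).

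Hepatocyte genes had one in 2 of 20 cases in U2OS and 0 of 20 in K562 (adjusted exact p = 0.0185 and 0.0050). Neuronal genes had one in 3 and 1 of 20 (0.0576 and 0.0350), and the K562 value was 0.0576 without K562 replicate B. HOX genes, which set position along the body axis, had one in 7 and 3 of 39 (0.0208 and 0.0078). HOXC13 had 95.9 ± 0.937 in U2OS and 40.7 ± 6.44 in K562, and HOXB9 had 18.8 ± 16.8 and 69.7 ± 39.5 (SD, n = 3). None of these tests passed with lists of equal length. With the better-scoring 50% of peaks, the adjusted exact p in K562 was 0.0575 for the hepatocyte and neuronal lists and 0.0771 for HOX genes.

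Promoter quadruplex genes, oncogenes and growth factors with well-studied promoter quadruplexes, had a site in 8 of 15 cases in U2OS and 4 of 15 in K562 (adjusted exact p = 0.346 and 1). MYC had sites in all 3 replicates of both lines, at 57.6 ± 13.8 and 43.1 ± 9.55 (SD, n = 3). Its U2OS site at chromosome 8, 127735978 to 127736330, centred at -66 bp and held no canonical motif. BCL2 was listed in 7 U2OS libraries and 0 K562 libraries, and VEGFA in 9 and 3. KIT, TERT and RET were listed in none. The 9p21 genes CDKN2A, CDKN2B and MTAP had sites in 0 of 3 cases in both lines (0.346 and 0.592).

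**Figure D4:**
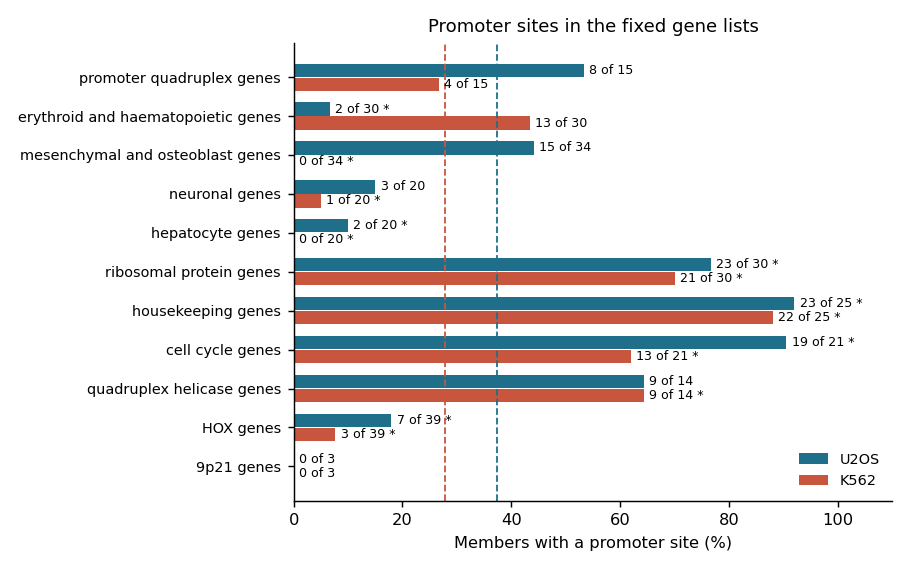
Members of each fixed gene list with a promoter site (horizontal axis, %) in U2OS and K562, with counts beside the bars. Asterisks mark lists whose adjusted Fisher exact p lay under 0.05, and dashed lines mark the share of all genes, 37.3% in U2OS and 27.7% in K562.

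Lists for the lineage of each line were compared between lines. Erythroid and haematopoietic genes had a site in 13 of 30 cases in K562 and 2 of 30 in U2OS, with 11 in K562 alone and 0 in U2OS alone. TAL1, a master regulator of blood formation, reached 70.9 ± 15.1 in K562 (SD, n = 3) at chromosome 1, 47232271 to 47232544, and was listed in no U2OS library. The related gene LYL1 (52.9 ± 19.3), the corepressor gene CBFA2T3, the erythroid factor gene KLF1, the embryonic globin gene HBZ and the erythropoietin receptor gene EPOR were also listed in K562 libraries alone. The globin genes HBE1 and HBG2 (25.7 for both) rest on 1 shared site at chromosome 11, 5505659 to 5505770, which counts as 2 of the 11 genes in K562 alone. Promoters were counted at any annotated start, so this site may lie far from the main start of either gene. NFE2 and ZFPM1 had sites in both lines, and GATA1 was listed in no library. U2OS peaks were also listed for other members, such as GFI1B (6 U2OS and 5 K562 libraries) and ITGA2B (5 and 6). A site in K562 alone therefore means no U2OS consensus site, and not that U2OS libraries had no peak.

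Mesenchymal and osteoblast genes had a site in 15 of 34 cases in U2OS and 0 of 34 in K562. Listed in all 9 U2OS libraries were CALD1, TPM1, CCN1, SPARC, the collagen gene COL1A1 (84.3 ± 4.89), the intermediate filament gene VIM (85.0 ± 3.76), the caveolar gene CAVIN1 (87.8 ± 5.15), CCN2 (85.1 ± 8.44) and the receptor gene AXL (84.5 ± 6.46). Peaks short of a consensus site were also listed in K562 libraries, in 3 for VIM and TPM1, 4 for AXL and 1 for COL1A1 and CAVIN1. The osteoblast regulator gene RUNX2 had sites in 0 of 3 replicates of both lines.

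Against other genes, the erythroid list was low in U2OS (adjusted exact p = 0.00065, or 0.324 with lists of equal length) and did not pass in K562 (0.0855), where it passed with the deposited line lists (53.3%, 0.0444), a setting chosen after seeing the data. The mesenchymal list was low in K562 (8.6e-05) and did not pass in U2OS (0.526). Among genes with a site in exactly 1 line, the erythroid list differed towards K562 (adjusted exact p = 1.3e-06). The mesenchymal list did not pass towards U2OS (exact p = 0.0295, adjusted 0.162). The other 9 lists had adjusted values of 0.915 or more. The erythroid difference did not pass with lists of equal length (2 genes, adjusted exact p = 1) or with sites required in all 3 technical libraries (3 genes, 0.135), and without K562 replicate A the K562 share was 20%. The mesenchymal difference passed without U2OS replicate A, B or C (0.0407, 0.0046 and 0.0052).

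Sites per chromosome were compared because both lines carry gains and losses of DNA. Relative to the ratio of the whole genome, K562 sites were most abundant on chromosome 6 (1.66, range over the 9 pairs of replicates 1.497 to 1.67) and chromosome 19 (1.59, 1.36 to 1.82). They were least abundant on chromosome 13 (0.557, 0.486 to 0.746), chromosome 14 (0.610) and chromosome 10 (0.672). On 20 of 23 chromosomes all 9 pairs of replicates lay on the same side of 1, and the exceptions were chromosomes 9, 11 and 12. No test was run, since chromosomes are not replicates.

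**Figure D5:**
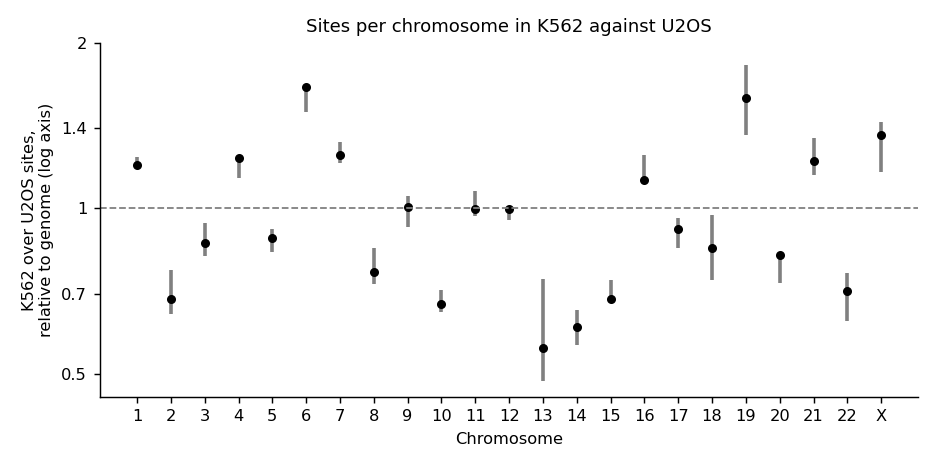
K562 over U2OS consensus sites per chromosome, divided by the ratio of the whole genome (vertical axis, log scale, no unit). Points are consensus sites and lines the range over the 9 pairs of biological replicates; chromosomes 6 and 19 lie highest and chromosome 13 lowest.

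Sites over 10 kb from any gene start, inside or outside genes, were mostly found in a single line. U2OS alone had 1928, K562 alone 579, and 27 were shared. The highest U2OS sites lay in BAHCC1, at chromosome 17, 81419338 to 81419696 and 81422711 to 81423786, and in the myoferlin gene MYOF, at chromosome 10, 93458717 to 93459140. The highest K562 sites lay at chromosome 17, 82345193 to 82345524, outside annotated genes, in the ion channel gene ASIC2 at chromosome 17, 33905348 to 33905662, and in the glycosyltransferase gene GALNT2 at chromosome 1, 230127134 to 230127421. The highest shared sites lay at chromosome 19, 2061478 to 2061767, in SDR42E2 and in HPD. Each of the 9 was listed in all 9 libraries of its line, and the sites of a single line in 0 libraries of the other. These counts were not tested.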

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

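No single library stood far from the others of its line in any of the 12 sets of values tested; groups of 3 biological replicates were too small for this test. No test in this part was chosen after its result was seen, and no biological explanation was tested here. The results below are signals in data outside the comparisons.

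The deposited K562 lists hold stretches that the K562 libraries do not give. On chromosomes 1 to 22 and X the deposited line list has 13413 stretches, and 3711 of them contain no site rebuilt from the 9 libraries. Of these, 41.7% lay at promoters, 5.36% held a canonical motif and 25.1% overlapped a U2OS site. The deposited lists of K562 replicates A, B and C held 17336, 10369 and 15853 stretches against 13236, 7320 and 11974 rebuilt ones, while every deposited U2OS list was rebuilt exactly.

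Peaks on the mitochondrial genome were listed in 16 of the 18 libraries, from 15 in the lowest U2OS library to 35 in the highest of all libraries. No input values were used to set a background for them. Their median fold per library lay between 1.497 and 2.04, below the 10th percentile of nuclear peaks, which lay between 3.81 and 4.48.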

How the results depend on the processing

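Of 666 comparisons of 55 results with 24 alternative settings, 599 kept their direction and their side of the threshold or stayed within the allowed range, and 9 turned. Those with the deposited line lists (beyond the 2 results planned for them), without library K562 B2 and for gene families were chosen after seeing the data. The 599 are not a measure of robustness. Tests of 3 against 3 biological replicates, or with the replicate letters as a block, cannot pass the threshold, so they counted as kept whenever the direction held. With lists of equal length, the K562 lead in promoter share counted as kept at 3.28 percentage points against 9.70. The U2OS lead in motif share did so at 9.97 against 1.398, where keeping only the best-scoring peaks of the longer U2OS lists could itself widen the lead. The promoter and motif shares stayed above their backgrounds in both lines in each setting run, and the K562 overlap with U2OS stayed above its shuffles, at 39.1% to 57.7%. Turned were the ratio of sites per replicate with lists of equal length (0.964), the U2OS lead in motif share with 2 G per run (-1.43), the U2OS motif share of shared less unshared promoter sites in 200 bp windows (-10.5), and promoter quadruplex genes in K562 with a 2 kb promoter (33.3%). So were erythroid genes in K562 with equal lists (10%), with sites in 3 of 3 technical libraries (13.3%) and without K562 replicate A (20%), and mesenchymal genes in U2OS with equal lists (8.82%) and with 3 of 3 technical libraries (23.5%). Equal lists and stricter agreement leave fewer sites by construction; beyond that, the cause was not tested. With 1 replicate left out, erythroid genes in K562 ranged from 20% to 43.3%.

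Counts moved as follows. With the better-scoring 50% of peaks, consensus sites were 9554 in U2OS and 4990 in K562, and restricted promoters 361 and 70. With equal lists they were 3336 and 3521, restricted promoters of U2OS 102, lists that differed from other genes 9, and lists that differed between lines 0. With 3 of 3 technical libraries they were 10482 and 5195, restricted promoters 212 and 49, and lists between lines 0. With 3 of 3 biological replicates consensus sites were 11987 and 6025. With 1 replicate left out, K562 sites ranged from 6400 to 10169, U2OS-only promoters from 620 to 959, K562-only promoters from 130 to 214, and lists between lines from 1 to 2. The deposited line lists gave 3 lists between lines. In K562 the hepatocyte and neuronal lists also missed the threshold with 3 of 3 technical libraries (adjusted exact p = 0.0562 for both), and the neuronal list with a 2 kb promoter (0.106). In U2OS so did the HOX list with a 2 kb promoter (0.0714) and the hepatocyte list with 3 of 3 technical libraries (0.0562). The U2OS helicase list passed with the better-scoring 50% of peaks (0.0225), equal lists (0.0486) and 3 of 3 technical libraries (0.0242) or biological replicates (0.0466). The 12 named U2OS-only promoters were kept in each setting, and the K562-only ones except for 1 with equal lists, 3 with a 500 bp promoter and 1 with a 2 kb promoter. With a biological replicate left out, this was fixed in advance, since the rule then has fewer requirements and restricted counts cannot fall. The named promoters were also picked for high percentiles, which makes them likely to stay in stricter peak lists. With the replicate letters as a block, paired exact sign-flip p values were 0.25 for peaks, sites and promoter share and 0.5 for motif share, where 0.25 is the smallest possible. The deviations of same-letter replicates correlated at -0.0475, -0.072 and 0.0138, so no pairing by letter was seen. Such values cannot show that same-letter replicates were handled apart. Depth is unknown, and the peak threshold limits each absence.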

Other observations

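The tests of gene families, the test of list length as the source of the U2OS excess and the test around BCR and ABL1 were chosen only after the results they concern had been seen. Histone genes of a single stretch of chromosome 6 carried sites mainly in K562. Of 90 histone genes, 27 had a promoter site in K562 alone, 1 in U2OS alone and 11 in both, the lowest p of the 24 families tested (adjusted exact p = 4.3e-15). Of the 27, 25 lie in that stretch, and 2 of the 35 histone genes elsewhere had a site in K562 alone. H2BC13, H2AC13, H4C3, H2BC8 and H2AC8 on chromosome 6, and H2AC25 and H2BC26 on chromosome 1, were listed in all 9 K562 libraries and in no U2OS library. The variant genes H2AZ1, H2AZ2, H3-3A and H3-3B were listed in all 9 libraries of both lines. Many histone genes have near-identical copies, so single members are uncertain. A site that lies in the promoters of 2 neighbouring genes counts for each, here and in the comparison by stretch below. H2BC12 and H2AC12, for example, were both listed in 7 U2OS and 9 K562 libraries. Such genes are not independent, so the p values may be too small. In K562, 2 of 35 sites at histone promoters (5.71%) held a canonical motif, against 14.9% of other promoter sites (exact p = 0.155). Zinc finger genes with the ZNF prefix were the other family that passed, with 44 genes that had a site in K562 alone and 77 in U2OS alone (odds ratio 1.90 towards K562, adjusted exact p = 0.0172). With lists of equal length, 25 histone genes had sites in K562 alone and 0 in U2OS alone. The ZNF difference did not pass with the better-scoring 50% of peaks (exact p = 0.150) or with sites in all 3 biological replicates (exact p = 0.138). Family tests did not account for chromosome, and the relative site ratio ran from 0.557 on chromosome 13 to 1.66 on chromosome 6. The ZNF difference was not tested apart from such differences, which include relatively more K562 sites on chromosome 19 (1.59).

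Windows of 10 Mb differed between lines within chromosomes. On chromosome 9, the window from 20000001 to 30000000, which holds the 9p21 genes, had 21 U2OS sites and 0 K562 sites. On chromosome 8, the window from 130000001 to 140000000 had 94 and 9 sites. On chromosome 7, the window from 120000001 to 130000000 had 18 and 42 sites. On chromosome 10, the window from 110000001 to 120000000 had 105 and 14. These windows were picked from the values and were not tested.

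The promoters restricted to a line numbered 709 over both lines and at most 6 in the other 9 splits of the 6 replicates; with 10 splits, of which 1 gave as many, a share under 0.05 cannot be reached. The peak threshold with shorter K562 lists stays open: U2OS-only promoters had a median percentile of 55.4, above the bound of 50 set beforehand. That bound was too low, since promoters in 3 of 3 U2OS replicates with a K562 peak had 69.9, and the restricted ones rank below them. With lists of equal length the ratio of U2OS-only to K562-only promoters was 0.703 against 4.72 in the full lists, but equal lists bring the site totals of the lines together by construction, so this decides nothing about list length. Line biology, sequencing pool and depth cannot be told apart here.

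The share of sites with a motif stood above random places in both lines. Base composition as the whole source is argued against, since dinucleotide shuffles of the sites held motifs less often, by 1.83-fold in U2OS and 1.62-fold in K562. Placement anywhere within promoter windows is argued against too as the whole source. Random placements held motifs less often, by 2.29-fold and 1.64-fold, with promoter sites put in promoter windows and other sites outside them. These placements did not follow the position of sites near gene starts or the kind of promoter, so finer promoter location stays open. Motif recognition by the nanobody may contribute: the motif share increased with fold rank in promoter and other sites of both lines, with a lowest median rho of 0.802. Neither peak width nor base composition was held fixed over the ranks, and either could give the same increase. Sequence preference without folding was not tested, and most sites held no canonical motif.

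The site ratio between lines differed by chromosome, and DNA dosage may contribute, since promoter and other sites departed together over the 23 chromosomes (rho = 0.887, Pearson r = 0.848, permutation p = 1e-05 for rho, the smallest possible; chromosomes are not replicates). Dosage of part of the short arm of chromosome 6 as the source of the histone sites cannot be told apart from a histone effect. Between 25726562 and 27893425, 25 of 55 histone genes and 4 of 20 other genes had a site in K562 alone (exact p = 0.0613). The relative ratio was 7.09 there, 3.39 in the sequence before it and 1.34 in the rest of chromosome 6. In the next 10 Mb windows from 30000001 it was 1.45, 1.21 and 0.626. A dosage difference between lines that is even over the whole arm is argued against as the only source of these ratios. The ratios cannot tell a change in K562 from a change in U2OS. An even gain in K562 and a gain of the outer part of the arm therefore both stay open. Extra copies next to the BCR-ABL1 fusion also stay open, since the odds ratio towards the kept side was 11.2 at BCR (112 K562 and 66 U2OS sites kept, 32 and 211 on the other side) and 1.07 at ABL1 (exact p = 0.752). No copy number values were used.

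A preference for motifs on the coding strand downstream of gene starts was tested and stays undecided. In U2OS 155 of 266 sites (58.3%) had the motif on the coding strand against 58.8% of control windows, an odds ratio of 0.979. In K562 77 of 123 sites (62.6%) did against 58.7%, an odds ratio of 1.18 (exact p = 0.406).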
